A study of Homo sapiens with 22 samples.

How the data were processed

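Total RNA of HEK293 clones was sequenced on an Illumina HiSeq instrument, per the labels' protocols, with no treatment. The submitters' processing notes name FastQC, cutadapt, TopHat2, Bowtie and the hg38 build, without versions or roles; the counting tool, annotation, strand setting, filter and scaling are not given in the sources used here. The deposited table holds log2 CPM for 15797 genes in 22 libraries, as found from its values.

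In each library the lowest value was -1.45, or 0.367 CPM on the linear scale, and the values above it were whole multiples of 1 step per library within a tolerance of 0.01 for 100% of genes. Whole reads could therefore be recovered, 4951081 to 6197084 per library, and the floor equals a prior of 2 reads at the mean library size of 5448078. Library size factors implied by the steps were 0.941 to 1.08 times these totals. Fold changes are on the log2 scale with this prior included and so understate the change of low genes. The design had assumed counts. As the unit is log2, the planned limma-trend test was used on the deposited log2 values as they are, in place of adding a pseudocount of 1, and count models were not run as the main test.

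The 2 libraries of a clone were averaged. Genes with at least 1 CPM, the prior of 0.367 CPM included, in at least 4 of the 10 BDD and FL clones were kept (15611). BDD and FL clones were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. The line titled HEK 28 entered only a fit over all 11 clones that shared one estimate of the spread. F8 was also tested by an exact permutation test. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 and with an estimated one, and lists with fewer than 3 measured genes were not tested. The correlation of F8 with a list score used exact permutations over all pairings. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Gene positions, types, lengths and GC content came from GENCODE 29 on GRCh38, which held all 15797 identifiers; 1272 genes had no symbol in the table, and 1259 of them were named from the reference.

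The named genes follow a rule fixed before the data were examined. They are F8, LMAN1, MCFD2, HSPA5, DDIT3, XBP1 and SURF4, the 10 highest and 10 lowest log2 fold changes among named genes with an adjusted p below 0.05, a mean of at least 2 log2 CPM and no overlap between clones, and up to 4 members of smallest p from each list. Some of these members are not given here. Where no member passed, the 1 of smallest p was to be given. Other genes are said to be chosen after seeing the data where they appear.

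The test was tested on simulated reads for the BDD and FL comparison, with 200 of 15611 genes changed. It recovered 28.4% of 67 genes changed 1.5-fold, 70.1% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, and 3.76% of its calls were unchanged genes. The changed genes had a mean of at least 2 log2 CPM, and simulated libraries of a clone differed only by sampling noise. Libraries a and b of a clone differed by more than sampling noise (chi-square per gene 5.82 to 46.4), so none was counted as a repeat of another. The letters a and b carried no pairing between groups: deviations of libraries with the same letter in different groups had a mean correlation of 0.0046, and those with different letters -0.0037.

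Alternatives covered the scaling (median of ratios, library totals), the filter, the pseudocount (1 and 0.1), the unit (libraries as separate samples, with the letter as a block, or with the clone as a random block), single libraries, each clone left out, the line titled HEK 28 as an FL clone, F8 as a covariate or left out of the library size, and stricter thresholds. Chosen after seeing the data were limma-voom on recovered reads, clone weights, fits without doubted libraries or without BDD clones 7 and 13, and a fit after removing each clone's trend on expression level, GC content, transcript length and gene span by regression splines. Levels of genes that could identify sex were left out.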

Results

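The study set out to learn how removing the B domain of coagulation factor VIII changes the cells that make and secrete it. RNA was sequenced from clones of HEK293, an established human embryonic kidney line, that carried either B-domain deleted factor VIII (BDD) or the full-length protein (FL). There were 6 BDD clones (numbers 1, 2, 7, 12, 13 and 27) with 12 libraries and 4 FL clones (numbers 4, 7, 9 and 10) with 8 libraries, each clone with a library a and a library b. The libraries of BDD clone 2 were titled "oldbdd", where the other BDD titles read "bdd", and the labels do not explain the difference. A further line with 2 libraries was titled HEK 28 while its genotype label read full length, and it was kept apart. Library depth, recovered from the deposited values, ran from 4951081 to 6197084 reads, and 15611 genes passed the filter for the main comparison. The clone, as the mean of its 2 libraries, was the unit of the main tests. The labels do not say whether libraries a and b came from separate cultures, or clones from separate transfections. The p-values therefore measure the spread between the means of these clones, which includes the spread between libraries a and b. The p-values also take the clones as independent, which the labels do not settle.

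F8, the gene that encodes factor VIII (ENSG00000185010, chromosome X, 154835788 to 155026940 on GRCh38), was far more variable among BDD clones than among FL clones. Its level was 5.44 ± 2.18 log2 CPM (SD, n = 6) in BDD clones and 7.55 ± 0.35 (SD, n = 4) in FL clones. BDD clone 13 had the lowest level, 2.10, and BDD clone 7 the next, 3.75, while BDD clones 1 and 12 reached 7.74 and 7.43, within the range of the FL clones. The highest and lowest BDD clones differed 49.7-fold. The difference in means, -2.10 on the log2 scale, did not pass an exact two-sided permutation test over all 210 splits of the clones (p = 0.1), and limma gave an adjusted p of 0.061. The line titled HEK 28 had the highest level, 8.90, so no F8-free line was available as a background. The counts also include any reads from the native gene and are not corrected for the shorter BDD transcript. Counting that line as an FL clone gave -2.37 and an exact permutation p of 0.0346. With limma the adjusted p was 0.0219 without BDD clone 1 and 0.0294 without BDD clone 12, within a range of 0.00777 to 0.13 over all alternatives. Without both BDD clones 7 and 13, a choice made after seeing the data, the difference was -0.85 (limma adjusted p = 0.13).

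**Figure D1:**
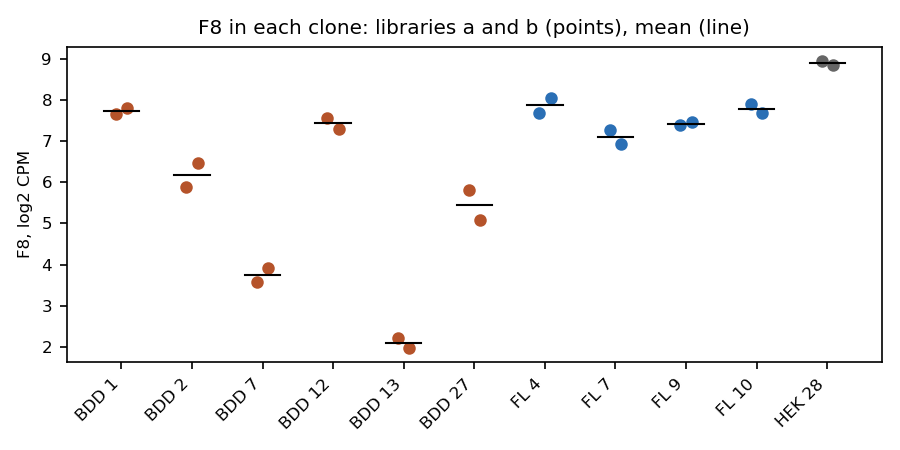
F8 in log2 CPM (vertical axis) for each clone or line (horizontal axis), with points for libraries a and b and a line at their mean. BDD clone means run from 2.10 to 7.74, FL clones stay between 7.11 and 7.87, and the line titled HEK 28 lies at 8.90.

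The transcriptomes of BDD and FL clones differed widely. Limma-trend called 5080 of the 15611 genes (32.5%), 2506 higher and 2574 lower in BDD clones, and of the 1724 that differed at least 2-fold 1243 were higher and 481 lower. INHBE, an inhibin beta subunit gene, was 19.1-fold higher, at 6.87 ± 0.33 log2 CPM in BDD clones (SD, n = 6) against 2.62 ± 1.04 in FL clones (SD, n = 4; log2 fold change 4.26, SE 0.34, adjusted p = 3.8e-06). FOSB, an immediate early transcription factor gene, was 17.3-fold higher, at 9.12 ± 0.23 against 5.00 ± 0.45 (log2 fold change 4.12, SE 0.18, adjusted p = 4.0e-09). The other genes among the 10 with the highest fold were ELSPBP1 (12.4-fold), the stress-induced cytokine gene GDF15 (9.28-fold), CFAP61 (8.65-fold), EGR2 (8.56-fold), the stress transcription factor gene ATF5 (8.49-fold), the tachykinin receptor gene TACR2 (8.03-fold), the mitochondrial leucine tRNA gene MT-TL1 (7.75-fold) and the phospholipase gene PLA2G1B (7.08-fold).

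Among the lowest genes, AKAP6, an anchoring protein gene, was at 1.76 ± 0.35 log2 CPM in BDD clones (SD, n = 6) and 5.69 ± 1.79 in FL clones (SD, n = 4), a log2 fold change of -3.93 (SE 0.55, adjusted p = 0.00015). INSIG1, a regulator of sterol synthesis, had a log2 fold change of -1.88 (adjusted p = 1.5e-05), and the neurofilament gene NEFM, one of the more abundant transcripts, one of -1.79 (adjusted p = 2.0e-05). BOLA3 (-2.52), which acts in mitochondrial iron-sulfur cluster assembly, ZNRD2 (-2.46), FUOM (-2.31), COPS7A (-2.07), the complex I gene MT-ND6 (-1.81) and MED20 (-1.77) followed. CTSF, which encodes cathepsin F, had -2.66 (adjusted p = 0.033) but was split among the BDD clones. It was at 3.46, 3.60 and 3.64 in clones 7, 13 and 27 and at 0.35, -1.45 and -0.74 in clones 1, 2 and 12, and its call was lost in 7 of the 10 fits that left out a clone (adjusted p up to 0.0699). MT-TL1 and MT-ND6 neighbour or overlap other mitochondrial transcripts, and the sources used here do not state strand, so their reads may be shared.

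Genes of the early secretory pathway were called lower more often than higher in BDD clones, in each list tested in the main fit. Protein-coding genes as a whole leaned the same way, with 2410 of 12898 lower and 1964 higher. Among all genes with a mean of 4 to 6 log2 CPM, 1173 of 5224 were lower and 640 higher. The lists of ATF6 and XBP1 targets and of Golgi genes did not pass camera. HSPA5, the main endoplasmic reticulum (ER) chaperone BiP, was at 8.61 ± 0.21 log2 CPM in BDD clones (SD, n = 6) and 8.71 ± 0.21 in FL clones (SD, n = 4), with an adjusted p of 0.58. LMAN1, the cargo receptor for factor VIII, had a log2 fold change of -0.12 (adjusted p = 0.42), its partner MCFD2 one of -0.42 (adjusted p = 0.038) and the cargo receptor SURF4 one of -0.38 (adjusted p = 0.013). XBP1, a transcription factor of the unfolded protein response, had 0.27 (adjusted p = 0.12). In the limma fit with per-clone trends removed, XBP1 had 0.71 (adjusted p = 0.00079). In that fit MCFD2 (-0.21, adjusted p = 0.26) and SURF4 (-0.15, adjusted p = 0.30) did not pass. The MCFD2 call was lost in 7 of the 10 fits that left out a clone, with an adjusted p of up to 0.119.

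Of 25 genes for N-linked glycosylation, 14 fell and none rose (14 fell when adjusted over the list alone), among them DAD1 (-0.72), OST4 (-1.37), DDOST (-0.91) and STT3B (-0.60), all parts of the oligosaccharyltransferase. Limma's camera test gave this list an adjusted p of 4.5e-05, and 0.12 with an estimated correlation. Removing per-clone trends on expression level, GC content and length moved its median from -0.46 to -0.26, with 8 genes lower (adjusted p = 0.022). Of 36 ER to Golgi transport genes, 11 fell and 1 rose, the same counts adjusted over the list alone; COPB2 (-0.64), TMED10 (-0.51), TMED2 (-0.81) and SEC22B (-0.67) had the smallest p (camera adjusted p = 0.0028, and adjusted p = 0.23 with an estimated correlation). Of 27 ER chaperones, lectins and oxidoreductases, 11 fell and 3 rose (13 and 3 adjusted over the list alone): the peroxiredoxin PRDX4 had -0.72 and the lectin chaperone CALR -0.67, while the oxidase ERO1B had 0.82 and ERP29 0.55. Camera gave an adjusted p of 0.022, and an adjusted p of 0.23 with an estimated correlation. Of 25 ER-associated degradation genes, 6 fell and 2 rose (6 and 2 adjusted over the list alone): UBE2J2 had -0.53, DERL3 -1.53 and VCP -0.38, and SEL1L 0.95 (camera adjusted p = 0.044, and adjusted p = 0.28 with an estimated correlation). Of 22 ATF6 and XBP1 targets, 8 fell and 2 rose (8 and 2 adjusted over the list alone), SDF2L1 (-1.16), CALR and PDIA6 (-0.56) among those lower and SEL1L among those higher, and the list did not pass (camera adjusted p = 0.081, and 0.45 with an estimated correlation). Of 22 Golgi O-glycosylation and sulfation genes, 4 fell and 2 rose (3 and 2 adjusted over the list alone), with GALNT2 at -0.66, SLC35A2 at -0.69, GALNT3 at 0.58 and the protease FURIN at 0.56, and the list did not pass (camera adjusted p = 0.52). Calls for these 4 genes were lost when 1 or more clones was left out (adjusted p up to 0.0554 for GALNT2, 0.0843 for SLC35A2, 0.0525 for GALNT3 and 0.0914 for FURIN). The ER chaperone, ER-associated degradation and ER to Golgi calls did not remain when the per-clone trends were removed (adjusted p = 0.37, 0.63 and 0.37). Their medians went from -0.31 to -0.18, from -0.30 to -0.09 and from -0.23 to -0.06.

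Of 30 genes of the integrated stress response, the PERK and ATF4 branch, 13 rose and none fell (13 adjusted over the list alone), with ATF5 (3.09), ATF3 (1.64), the phosphatase subunit PPP1R15A (1.28) and the pseudokinase TRIB3 (1.15) having the smallest p. DDIT3, which encodes CHOP, was at 4.64 ± 0.36 log2 CPM in BDD clones (SD, n = 6) and 3.56 ± 0.43 in FL clones (SD, n = 4; log2 fold change 1.08, SE 0.22, adjusted p = 0.0022). Camera gave the list an adjusted p of 1.4e-06, and 0.23 with an estimated correlation. Of 18 p53 targets, 8 rose and none fell (9 adjusted over the list alone), including the cell cycle inhibitor CDKN1A (1.17), GDF15 (3.21), ZMAT3 (1.16) and RRM2B (0.93), with a camera adjusted p of 0.0029 and 0.28 with an estimated correlation. Of 15 type I interferon response genes, 7 rose and none fell (7 adjusted over the list alone), with BST2 at 2.48, IRF7 at 1.60, IFI44L at 1.05 and ISG15 at 0.69 (camera adjusted p = 0.023, and adjusted p = 0.28 with an estimated correlation).

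Of 29 proteasome subunits, 12 fell and none rose (14 adjusted over the list alone), with PSMB1 at -0.86, PSMD1 at -0.71, PSMD6 at -1.06 and PSMB3 at -0.77 (camera adjusted p = 4.9e-06, and adjusted p = 0.12 with an estimated correlation). Of 20 NRF2 oxidative stress genes, 8 fell and 2 rose (9 and 2 adjusted over the list alone): TALDO1 of the pentose phosphate pathway had -1.35, the superoxide dismutases SOD1 and SOD2 had -0.89 and -0.64, and thioredoxin, TXN, had -1.70 (camera adjusted p = 0.012, and adjusted p = 0.23 with an estimated correlation). With the per-clone trends removed, the proteasome median went from -0.35 to -0.09 and its call was lost (adjusted p = 0.12). The NRF2 call was lost too (adjusted p = 0.11), but its median went from -0.25 to -0.40 and 9 members were lower. Of 19 heat shock genes, 6 fell and 1 rose (6 and 1 adjusted over the list alone), HSPD1 at -0.67 and DNAJB1 at 0.57, without passing (camera adjusted p = 0.069). With the per-clone trends removed 4 fell and 4 rose, and the list median went from -0.33 to -0.01. HSPA1B (-1.17) and HSPA1A (-0.98) are near-identical copies whose reads may be split, and the HSPA1A call was lost when 1 clone was left out. Apoptosis effectors went both ways, 4 of 22 up and 5 down (4 and 5 adjusted over the list alone), with HRK at 1.04, TNFRSF10B at 0.65, CYCS at -0.81 and BIRC5 at -0.62 (camera adjusted p = 0.73). Of 27 autophagy and lysosome genes, 5 rose and 5 fell (6 and 5 adjusted over the list alone), the regulator TFEB at 1.52 and the receptor SQSTM1 at 0.77 against LAMP1 at -0.47 (camera adjusted p = 0.73). The median of this list was -0.05 and its mean 0.0062. Of 10 measured NF-kappa-B and inflammatory genes, 4 rose (4 adjusted over the list alone): RELB had 1.15, PTGS2 1.67, IRF1 0.65 and NFKB1 0.36 (camera adjusted p = 0.15). The IRF1 and NFKB1 calls were lost when 1 or more clones was left out (adjusted p up to 0.0721 and 0.0601).

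Of 25 nuclear-encoded oxidative phosphorylation genes, 21 fell and none rose (22 adjusted over the list alone), with the ATP synthase genes ATP5MC1 at -1.21 and ATP5F1B at -0.89 and the respiratory chain gene NDUFA4 at -1.01. This was the list whose call held with an estimated correlation (camera adjusted p = 3.8e-11, and adjusted p = 0.036 with an estimated correlation). With the per-clone trends removed its median was -0.45 and 15 genes were lower (adjusted p = 1.7e-06). Of the 15 genes in the list of mitochondrially encoded genes, 9 fell and none rose (10 adjusted over the list alone), MT-RNR1 at -1.09, MT-ATP6 at -0.79 and MT-ND4L at -0.69 (camera adjusted p = 1.4e-05, and adjusted p = 0.28 with an estimated correlation). This list leaves out some mitochondrially encoded genes, MT-TL1 among them. Of all 25 that were analysed, 12 were lower and 2 higher. Mitochondrially encoded genes held 6.99% ± 0.723 of reads in BDD clones (SD, n = 6) and 9.20% ± 0.295 in FL clones (SD, n = 4), without overlap (exact two-sided permutation p = 0.0048, the smallest possible). Of 22 cholesterol synthesis genes, 16 fell and none rose (16 adjusted over the list alone), with a median of -1.02; INSIG1, MSMO1 (-1.42) and FDFT1 (-1.27) were among them (camera adjusted p = 2.1e-07, and adjusted p = 0.23 with an estimated correlation).

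Of 32 S and G2M phase genes, 17 fell and 1 rose (18 and 2 adjusted over the list alone), among them CCNB1 (-1.35), AURKA (-1.09), PLK1 (-1.09) and CDC20 (-0.96), which act in mitosis. Camera gave an adjusted p of 5.4e-05, 0.16 with an estimated correlation and 0.12 with the per-clone trends removed, where the median went from -0.38 to -0.13. Of 25 glycolysis and hypoxia genes, 8 fell and 5 rose (10 and 5 adjusted over the list alone), LDHA at -1.60, PGK1 at -0.97 and ALDOA at -0.88 against the glucose transporter SLC2A3 at 1.39 (camera adjusted p = 0.11). Of 44 cytosolic ribosomal protein genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone), RPS27 at 0.81, RPS19 at 0.71 and RPL3 at 0.46 (camera adjusted p = 0.0043, and adjusted p = 0.44 with an estimated correlation); reads of these genes may be shared with their pseudogenes.

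Lists of tissue and cell type genes did not pass camera. Renal epithelial and developmental genes had 4 of 14 higher and 2 lower (4 and 2 adjusted over the list alone), with the keratins KRT8 (1.83) and KRT18 (0.97) and CD24 (1.85) higher and WT1 (-1.27) lower (camera adjusted p = 0.33). Neuronal and adrenal genes had 5 of 11 higher and 3 lower (5 and 3 adjusted over the list alone): MAP2 (2.01) and ENO2 (1.40) were higher and the neurofilament genes NEFM and NEFL (-1.08) lower (camera adjusted p = 0.39). Extracellular matrix and adhesion genes had 6 of 27 higher and 3 lower (7 and 3 adjusted over the list alone), COL5A1 at 1.08, MMP2 at 1.47 and COL6A1 at 0.69 against CD44 at -1.52 (camera adjusted p = 0.95). The median of this list was -0.09 and its mean 0.01. Coagulation and factor VIII partner genes had 3 of 13 higher and 3 lower (3 and 4 adjusted over the list alone), with F10 at 1.27, LRP1 at 0.80 and PROCR at -0.85 (camera adjusted p = 0.76). Here too median and mean differed in sign (-0.10 and 0.03). F10 and LRP1 lost their calls when 1 or more clones was left out (adjusted p up to 0.0948 and 0.067). Of 4 measured fibroblast genes COL1A1 had 0.95 and VIM -0.81 (1 higher and 1 lower, also adjusted over the list alone, camera adjusted p = 0.86). Of 4 endothelial genes FLT1 had 0.62 (1 higher, also adjusted over the list alone, camera adjusted p = 0.16). Only 2 of 12 leukocyte genes were measured, too few for a list test. The call for VIM was lost in 7 of the 10 fits that left out a clone (adjusted p up to 0.126). None of 14 hepatocyte genes was among the genes analysed.

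The direction of change followed expression level and gene class. Of 2245 genes with a mean below 1 log2 CPM, 472 were higher and 82 lower in BDD clones, whereas of 2501 genes above 6 log2 CPM 264 were higher and 753 lower. Long non-coding RNA genes that overlapped a protein-coding gene had 253 of 1151 higher and 66 lower, and those between coding genes 196 of 873 higher and 44 lower. Of the 3903 genes in the quartile of longest span 739 were higher and 271 lower (median 0.14), and the medians of the other quartiles lay between -0.08 and -0.02. Removing per-clone trends on level, GC content, length and span takes out such patterns by construction. Genes below 1 log2 CPM then had 172 higher and 189 lower, and those above 6 had 399 and 463. The quartile of longest span then had 430 higher and 410 lower (median 0.005). At 4951081 reads per library, BDD clones had reads in 15624 ± 37.0 genes (SD, n = 6) and FL clones in 15430 ± 43.8 (SD, n = 4), without overlap (exact two-sided permutation p = 0.0048). Chromosome 11 had 70 of 841 genes higher and 210 lower, and chromosome 15 had 111 of 533 higher and 46 lower. Leaving out BDD clones 7 and 13, a choice made after seeing the data, gave 82 and 131 on chromosome 11 and 64 and 53 on chromosome 15.

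**Figure D2:**
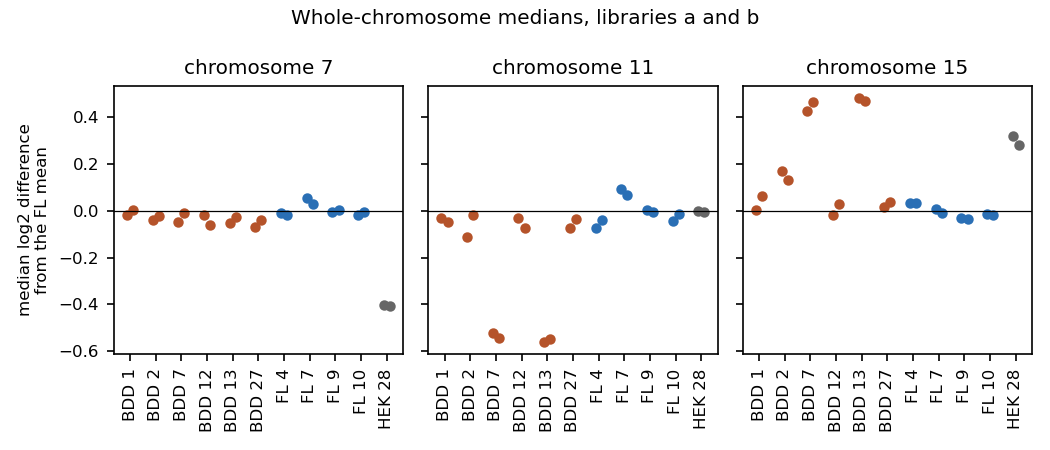
Median log2 difference from the FL mean (vertical axis) over all genes of chromosomes 7, 11 and 15, after subtracting each library's median over all genes; points are libraries a and b of each clone (horizontal axis). BDD clones 7 and 13 lie at -0.53 and -0.58 on chromosome 11 and at 0.46 and 0.47 on chromosome 15, and the line titled HEK 28 at -0.40 on chromosome 7.

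Against the line titled HEK 28, BDD clones had 389 genes higher and 360 lower of 15639 (749 in all). FOSB (4.48 on the log2 scale, adjusted p = 2.2e-06) and MT-TL1 (2.84) were higher in BDD clones, as were EGR3 (3.81), EGR1 (3.07) and JUND (1.76), which were chosen after their values were seen. Of the nuclear-encoded oxidative phosphorylation genes 7 of 25 were lower and none higher, and of the S and G2M phase genes 6 of 32 were lower and none higher. Of the integrated stress response genes 2 of 30 were higher and none lower (median 0.17), and the median of FL clones relative to this line was -0.39. Between FL clones and this line limma called 0 genes, and 800 genes had an unadjusted p below 0.05. A single line was assumed to vary as the clones of the other groups do, and both comparisons used it, so their difference was not tested.

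The median SD between libraries a and b was 0.35 log2 CPM in BDD clones and 0.26 in FL clones, and the SD between clones that was left after subtracting the part due to libraries was 0.14 and 0.16. This part between clones was the larger in 25.3% of genes in BDD clones and 37.6% in FL clones. Of the 22 libraries, 14 correlated best with the other library of their clone, and all 22 with a library of their own group. Libraries BDD 2 a and b correlated least (Spearman rho 0.914), then BDD 12 a and b (rho 0.955), and other pairs reached up to 0.981. Without libraries BDD 2 b and BDD 12 a, limma called 4383 genes, and 4101 of the 5080 kept their call.

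Across the 6 BDD clones, F8 level was not shown to follow the mean z score of the ATF6 and XBP1 targets. Pearson's r was 0.54 (exact permutation p = 0.27, 0.40 adjusted over 3 such relations) and Spearman's rho 0.54 (exact permutation p = 0.30). Without the 2 clones farthest from the median F8 level r was -0.08 (exact permutation p = 0.96, n = 4). For the integrated stress response r was -0.11 (exact permutation p = 0.82, 0.82 adjusted) and rho -0.43 (exact permutation p = 0.42), and without the 2 clones r was -0.83 (exact permutation p = 0.29, n = 4). For immediate early genes, a list chosen after seeing the data, r was 0.60 (exact permutation p = 0.22, 0.40 adjusted) and rho 0.77 (exact permutation p = 0.10), and without the 2 clones r was 0.85 (exact permutation p = 0.29, n = 4). The 4 FL clones were too few for a correlation.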

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

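The test in this part, whether the gap from the highest or lowest clone to its nearest neighbour is large for the range of its group, was fixed before the data were examined. The genes and lists chosen after seeing the data, NDUFA3 among them, were added to it later. Each set of clone values held 1 gene, list or library measure (genes detected, mitochondrial share or reads) in 1 group. Of 336 such sets, 11 held such a clone, and chance alone gives about 16.8.

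Among FL clones, PPP1R15A was highest in clone 9 (5.19 log2 CPM, next 4.81), UBE2J2 in clone 7 (7.32, next 6.98), SQSTM1 in clone 7 (6.68, next 6.09) and MSMO1 in clone 7 (6.29, next 5.40). IRF1 was lowest in FL clone 4 (3.24, next 3.56). NDUFA3 was highest in FL clone 10 (7.08, next 7.04). The N-glycosylation list median was highest in FL clone 9 (0.066, next -0.01) and the endothelial list median lowest in FL clone 10 (-0.19, next 0.11), both relative to the FL mean. Among BDD clones, PRDX4 was lowest in clone 1 (6.70, next 6.96), PGK1 highest in clone 12 (7.07, next 6.68) and ATP5MC1 lowest in clone 27 (6.23, next 6.56).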

How the results depend on the processing

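Limma-voom on recovered reads, clone weights, the fits without BDD clones 7 and 13 and without the doubted libraries, and the removal of trends were chosen after the results were seen. The count of genes changed between BDD and FL clones stayed within 1.5 times 5080 under scaling, filter, pseudocount and unit alternatives, from 4930 with library totals only to 6480 with libraries as separate samples. It was 3592 without BDD clones 7 and 13, and ran from 3699 to 5325 with each clone left out in turn (lowest without FL clone 9). It fell to 2939 with only the a libraries, 3061 with only the b libraries and 3120 with F8 as a covariate (the cause was not tested), and by construction to 2715 at an adjusted p below 0.01 and 1724 with at least a 2-fold change. With the libraries separate and the letter as a replicate block, 6399 genes were called against 6480 without the block; the letters share only a name. Limma-voom on recovered reads summed per clone called 4875 genes, 4774 of them in common, and clone weights 5962. Removing per-clone trends left 4343 genes, 3490 in common. Library totals moved the share of higher calls from 49.3% to 55.7%. Against the line titled HEK 28, the BDD count fell from 749 to 85 at an adjusted p below 0.01. FL clones had 0 genes against that line in the main fit and in each scaling and filter run (800 at an unadjusted p below 0.05 in limma, near the share that chance gives). By construction they also had 0 at the stricter thresholds. The F8 difference of -2.10 passed with libraries as separate samples (permutation p = 0.0108), which ignores the clone, and was -2.37 with that line as an FL clone (exact permutation p = 0.0346). With each clone left out it ran from -2.56 to -1.44. In limma F8 also passed with the clone as a random block (adjusted p = 0.00777), which applies 1 correlation to all genes. It passed on recovered reads summed per clone (limma adjusted p = 0.048) and with clone weights (0.0247), but not in the main fit (0.061) or the scaling alternatives (0.0633 and 0.0641). Of 14 lists past camera, 1 held with an estimated correlation, 8 lists passed with the trends removed (the cause was not tested), and 13 to 16 did with a clone left out. The correlation of F8 with the ATF6 and XBP1 score passed in no setting, from -0.08 to 0.71. Of 130 named genes called, 16 lost their call when some clone was left out, and no named gene reversed. A filter at 1 CPM with the prior included is the main one, and a filter at 1 CPM without the prior was not run. A count-model Wald test was not run since the values are log2. In simulated reads at this depth and clone number, with 200 of 15611 genes changed, 28.4% of genes changed 1.5-fold were recovered. The real comparison called 5080 genes, which makes its cutoff on the unadjusted p less strict. The simulated share therefore does not carry over to it, though small changes may still go undetected.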

Other observations

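All tests in this part were chosen after the results were seen, as were its gene lists except the integrated stress response. Camera p-values of the lists chosen in this way were adjusted only among themselves, apart from the lists fixed beforehand. They cannot be ranked against the adjusted p-values of those lists. Of 32 immediate early genes, which respond within minutes to many stimuli, 22 were higher and 2 lower in BDD clones, with a median log2 fold change of 1.10 (camera adjusted p = 3.1e-11, and adjusted p = 0.055 with an estimated correlation). EGR1 was at 10.74 ± 0.31 log2 CPM in BDD clones (SD, n = 6) and 8.51 ± 0.33 in FL clones (SD, n = 4), EGR3 had a log2 fold change of 2.82, FOS 2.77, NR4A3 1.93 and JUND 1.53. MYC (-1.04) and KLF6 (-0.43) were the 2 that were lower, and their calls were lost in 2 and 6 of the 10 fits that left out a clone (adjusted p up to 0.0691 and 0.129). With the per-clone trends removed the median was 0.89, with 20 higher and none lower.

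Of 69 mitochondrial ribosomal protein genes 50 were lower and none higher (median -0.68; camera adjusted p = 2.8e-19, and adjusted p = 0.0027 with an estimated correlation), and with the per-clone trends removed 40 were lower (median -0.43). Of 38 complex I subunits and assembly factors 26 were lower and none higher (median -0.66; camera adjusted p = 1.0e-13, and adjusted p = 6.4e-04 with an estimated correlation), among them NDUFA3 (-1.13), and with the trends removed 21 were lower (median -0.46). Of 20 cytosolic aminoacyl-tRNA synthetases 3 were higher, SARS1 (0.72), WARS1 (0.78) and YARS1 (0.36), and 7 lower (median -0.07, camera adjusted p = 0.17), and with the trends removed 5 were higher and 4 lower (median 0.11). The YARS1 call was lost in 6 of the fits that left out a clone (adjusted p up to 0.134).

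Chance assignment of clones to groups is argued against as the source of the number of changed genes, if the clones are independent. Splits that mix the groups carry the group difference in their spread and so give few calls. Of 210 possible splits 100 were drawn. The real split of the 10 clones gave 5080 genes, the highest of the other splits drawn gave 10, and 1 of 100 splits, the real one, gave as many. Clones did not overlap between groups for 22.7% of genes, where chance gives 0.952%.

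Stress and immediate early genes were higher in every BDD clone than in every FL clone by list median, while the line titled HEK 28, labelled full length, had a stress response median of 0.39, above all FL clones and below the lowest BDD clone (0.46), but an immediate early median of -0.15, within the FL clones. FL clones had medians of at most 0.25 (stress response) and 0.20 (immediate early) above the FL mean. BDD clones 7 and 13, with the least F8, had stress response medians of 0.55 and 0.59 and immediate early medians of 1.12 and 0.62. More F8 RNA as the whole cause is therefore argued against. BDD clones 1 and 12, with F8 counts in the range of the FL clones, had stress response medians of 0.47 and 0.46 and immediate early medians of 1.32 and 1.25. Their counts are not corrected for the shorter BDD transcript, so these clones may not match FL clones in F8 RNA. Other effects of its amount stay open. Trends on expression level, GC content and length are argued against as well, since the stress response median was 0.65 after their removal and 0.48 before. A difference in harvest or handling between groups cannot be told apart from the construct, because the labels give no date; it would also place the lowest BDD clone, at 0.62 for immediate early genes, above all FL clones. A response to the BDD protein itself remains open and untested.

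BDD clones 7 and 13, which had the least F8, shared a lower level of chromosome 11 (medians -0.53 and -0.58) and a higher level of chromosome 15 (0.46 and 0.47), in both libraries of each clone. Whether these clones are independent of each other is therefore uncertain, although the tests counted them so. Of 253 pairs of clone and chromosome 7 lay beyond 0.3, and the 2 not named elsewhere here were chromosome 21 in BDD clones 1 (0.34) and 13 (0.33). All 28 of the 10 Mb bins tested on chromosome 11, 14 in each clone, lay below 0, which is consistent with a lost copy of the whole chromosome. This is a hypothesis from the same data, which DNA copy number or a karyotype, not analysed here, would decide. Trends on expression, GC content and length do not account for it, since the median of clone 13 was still -0.56 after their removal. The line titled HEK 28 had a chromosome 7 median of -0.40, below 0 in all 16 bins, and a chromosome 15 median of 0.29.

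Low-level and non-coding genes were called higher more often than lower in BDD clones, though most were not called. With the per-clone trends removed, long non-coding RNAs between coding genes had 138 higher and 66 lower, and those over coding genes 168 higher and 105 lower. Genes with a mean below 1 log2 CPM then had 172 higher and 189 lower, and those from 1 to 2 had 194 and 176. The trends include expression level, so their removal takes out this imbalance of low-level genes by construction. More reads in the BDD libraries are argued against. BDD clones had a mean of 5294320 reads and FL clones 5574830 (exact two-sided permutation p = 0.1). At equal reads BDD clones detected 194.7 more genes on average. Unspliced RNA from coding genes stays open, since the values point both ways: long non-coding RNAs over coding genes and those between them differed in median by 0.0087 (95% bootstrap interval -0.065 to 0.09, permutation p = 0.75), but genes of the longest span had a median of 0.14, above those of shorter genes. DNA or background reads could be a cause as well, since long non-coding RNAs between coding genes differed by only -0.073 from coding genes of the same level, and unexpressed genes, which would decide, were not analysed here. The filter used here took no account of group, and there were more BDD than FL clones. Low-level genes could therefore pass more easily when higher in BDD clones. The planned fit without this filter called 2514 genes higher and 2572 lower over all levels, against 2506 and 2574 with it. It kept 99.6% of the main calls, all with the same sign. Selection by this filter is therefore argued against as the source of the imbalance among called genes. Any filter applied by the submitters is not known and was not tested, so selection by it stays open. Detected genes were counted only within the deposited table. A biological difference between the groups is also open.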
